A study of Danio rerio with 4 samples.

How the data were processed

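H3K4me3, the trimethylation of histone H3 at lysine 4 that marks the promoters of active and poised genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in ZFL cells, a cell line from zebrafish liver. The 4 samples fell into 4 groups of 1 library each, by treatment (β-glucan, or Opti-MEM medium as the control) and by kind (H3K4me3 ChIP or input). Peak lists of the 2 ChIP libraries were analysed. No file of the 2 input libraries was used here. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated and libraries were made with a NEBNext Ultra II kit. The dose and duration of the treatment are not given in the sources used here.

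Per the submitters' processing notes, the tools were Trimmomatic, BWA, MACS2, deepTools and bedtools and the genome build was GRCz11. Their versions, settings and order are not given in the sources used here, nor is the treatment of duplicate reads. The authors deposited 1 list of peaks per ChIP library, and per the labels each list belongs to a single library. The lists carry no header, and their columns were read as the narrowPeak format. Each deposited peak had a start and an end, a summit offset, a whole-number score, a fold enrichment (a ratio of ChIP over background at the summit), a −log10 p-value and a −log10 q-value. The deposited score was 10 times the −log10 q-value rounded down, in 22119 of 22119 peaks of the β-glucan list and 24405 of 24434 of the Opti-MEM list. The lowest deposited −log10 q-value was 1.31 in both lists, next to 1.30 for a q-value of 0.05. Score, fold and q-value are the authors' values, and single values were not compared between the lists, since they depend on the depth of the library and of its input. They ranked and filtered peaks within each list, and the counts left by a common threshold depend on depth in the same way.

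Total reads per library are not given in the sources used here, so the coverage was read from the peaks themselves. A fold of (n + 1)/(λ + 1) and a Poisson p-value for more than n reads over a background of λ reads leave only n and λ unknown. With n whole, this gave the deposited −log10 p-value to within 0.001 for 22117 of 22119 β-glucan peaks and 24433 of 24434 Opti-MEM peaks. On data simulated with these same formulas, 100% of 2898 peaks returned their reads exactly. That checks the inversion only, and not whether the caller used these formulas. The recovered n is called the summit reads below. More summit reads than 2 times the shortest peak width were found in 359 β-glucan peaks and 395 Opti-MEM peaks. If reads were single-end and extended to the length of the shortest peak, this would need several reads at the same position, so whether the reads of tall peaks include duplicates is open. Its 95% exact Poisson intervals cover counting error only, since reads that are copies of the same fragment are not independent molecules. The recovered background never fell under a floor, which was read as the genome-wide mean coverage that a caller of this kind uses as its lowest background. The coverage of the libraries was compared through this floor alone. This floor was 0.134 reads in the β-glucan list (33.6% of peaks) and 0.141 in the Opti-MEM list (31.8%), a coverage ratio of 0.956. Coverage also depends on the length to which reads were extended, which is not given. The ratio of read numbers may therefore differ from this value.

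Peaks were compared by overlap of at least 1 bp (checked with bedtools 2.31.1; Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1). Chance overlap was taken from 100 circular shifts of the peaks along their chromosomes. Shares of peaks are given with 95% exact Clopper-Pearson intervals, which treat peaks as independent and say nothing of biological spread. Where exactly 1 peak of each list overlapped 1 of the other, summit reads were compared over pairs with 40 or more reads in sum, with 500 bootstrap draws of the pairs for the interval. With 1 library per treatment no test between treatments was possible and no p-value is given. Values describe these 2 libraries.

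The comparison of peak lists, its alternatives and the rule for named items were fixed before the data were examined. The analyses of recovered reads and backgrounds, the 1 Mb chromosome ends and the segments of chromosomes 4 and 16 were added after the data were seen. For some of the added tests the bounds were still written before their own result was known. By the rule the 3 widest peaks of each list, and the 3 peaks of each list with the highest −log10 q-value and no overlap in the other, are named. The design also held gene-level results: the genomic location of peaks, genes with a promoter peak, 15 pathway lists and 6 cell type lists, and promoter peak widths. The gene table at hand was for another build (GRCz12tu), and coordinates were not carried between builds. No gene was therefore assigned to a peak, and these results were not analysed here. Alternatives covered stricter q-values and folds, lists of equal length, reciprocal overlap of 50%, a 500 bp tolerance, merging of peaks within 500 bp and the 25 chromosomes alone. Coordinates are 1-based in GRCz11.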

Results

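The study compared H3K4me3 in zebrafish liver cells treated with β-glucan with that in cells kept in Opti-MEM, a reduced-serum culture medium. β-Glucan is a polysaccharide of fungal cell walls that is used to induce trained immunity, a lasting change of innate responses. The title places the work in trained immunity of hepatocytes, and the comparison asked whether the treatment altered this promoter mark. The β-glucan list held 22119 peaks and the Opti-MEM list 24434, each from 1 ChIP library. Which input each list was called against is not given in the sources used here. There were no replicates, so no difference below could be set against the spread between cultures. Both libraries were shallow: the median peak rested on 6 summit reads in each list, with an interquartile range of 4 to 14 reads in the β-glucan list and 4 to 13 in the Opti-MEM list. Peaks with under 10 summit reads made up 64.5% of the β-glucan list and 66.2% of the Opti-MEM list.

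H3K4me3 peaks lay on all 25 chromosomes in both treatments and covered 6.13 Mb after β-glucan and 6.61 Mb in Opti-MEM. The β-glucan list held 0.905 times as many peaks as the Opti-MEM list and covered 0.928 times the length. Opti-MEM peaks were more numerous on 25 of the 25 chromosomes, with a ratio of β-glucan to Opti-MEM peaks between 0.846 on chromosome 9 and 0.972 on chromosome 5. Peak widths were close, with a median of 188 bp after β-glucan and 184 bp in Opti-MEM. Peaks of 1000 bp or wider numbered 396 and 390. On unplaced scaffolds lay 593 β-glucan peaks and 616 Opti-MEM peaks. The coverage of the β-glucan library, estimated from the recovered background floor, was 0.956 times that of the Opti-MEM library, which goes in the same direction as the number of peaks.

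Most H3K4me3 peaks of either treatment overlapped a peak of the other by at least 1 bp, but under a reciprocal overlap of 50% only 48.3% of the β-glucan peaks and 43.7% of the Opti-MEM peaks did. Of the β-glucan peaks, 14464 (65.4%, exact interval 64.8 to 66.0%) overlapped an Opti-MEM peak, and 7655 did not. Of the Opti-MEM peaks, 14533 (59.5%, 58.9 to 60.1%) overlapped a β-glucan peak, and 9901 did not. Shifted positions gave an overlap of at most 1.13% and 1.02% in 100 shifts. Wide peaks were nearly all shared, with 97.0% of the β-glucan peaks and 95.9% of the Opti-MEM peaks of 1000 bp or more. The 100 peaks with the highest −log10 q-value of each list were all present in the other list, as were 996 of the top 1000 β-glucan peaks and 988 of the top 1000 Opti-MEM peaks.

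The peaks called in 1 list only were weak. They had a median of 4 summit reads in either list, against 10 for shared peaks, and 93.3% of those in the β-glucan list and 92.1% of those in the Opti-MEM list had under 10. Among peaks with 3 to 4 summit reads, 65.0% of the β-glucan peaks (exact interval 63.8 to 66.2%) and 72.1% of the Opti-MEM peaks (71.1 to 73.2%) had no counterpart. Among peaks with 100 or more summit reads this fell to 2 of 707 and 4 of 729. At this depth a peak missing from 1 list does not show that the mark was absent there. Restricting each list to peaks with 10 or more reads, a limit chosen after seeing the data, left 510 list-only peaks of 7859 after β-glucan and 785 of 8256 in Opti-MEM, against the full other list.

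**Figure D1:**
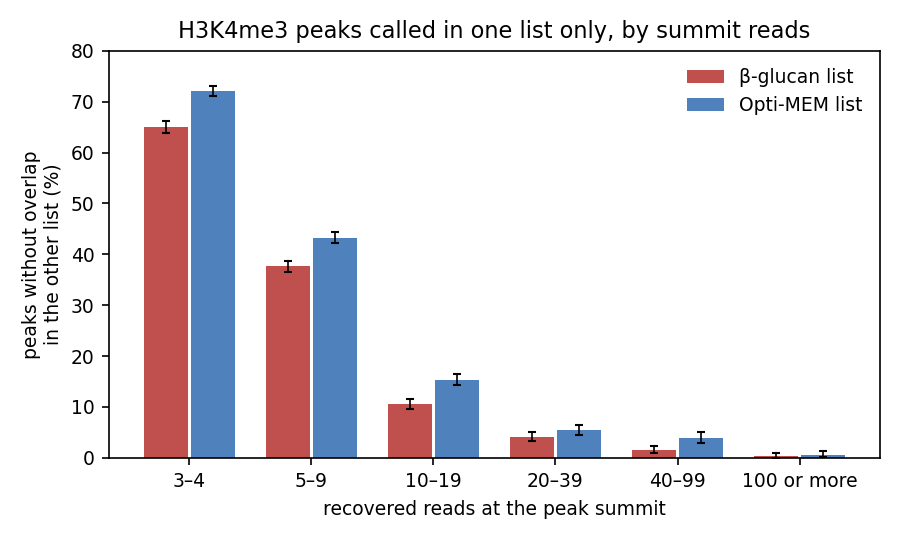
Share of H3K4me3 peaks without an overlap of at least 1 bp in the other list (percent, vertical axis) by recovered reads at the peak summit (horizontal axis), for the β-glucan and the Opti-MEM list. Bars are shares and error bars 95% exact binomial intervals; the share falls from 65.0% and 72.1% at 3 to 4 reads to 0.283% and 0.549% at 100 or more.

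At the taller shared peaks the height of the H3K4me3 signal was close after β-glucan and in Opti-MEM. Of 14893 overlapping combinations, 13386 paired 1 peak with 1 peak, and their summits lay a median of 15 bp apart. Over the 3799 pairs with 40 or more reads in sum, the median ratio of β-glucan to Opti-MEM summit reads was 0.966 (bootstrap interval 0.960 to 0.972), close to the coverage ratio of 0.956. The variance between the 2 libraries was 0.929 times the nominal counting variance (0.875 to 0.987). Summits are maxima, and simulated pairs with equal rates and an assumed summit shape gave 0.795 (0.722 to 0.875 over 20 draws), so the observed variance was above that of counting error in this simulation. Of these pairs, 5 lay at least 2-fold above the median ratio and 15 at least 2-fold below it. With 20 or more reads in sum, 95 of 6860 pairs lay above and 111 below by that much, and with 100 or more none of 1485 did. The remaining pairs, with fewer reads, were not compared. Pairs exist only where both libraries had a call, which limits the differences they can show. Over both lists, 76 list-only peaks with 40 or more reads were outside this comparison. The variance rose with height, to 1.12 times counting variance (1.00 to 1.24) over 687 pairs with 200 or more reads and 1.33 times (1.04 to 1.57) over 220 pairs with 500 or more, limits chosen after the data were seen. The median log2 ratio of peak widths over the 13386 pairs was 0, with an interquartile range of -0.18 to 0.17.

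**Figure D2:**
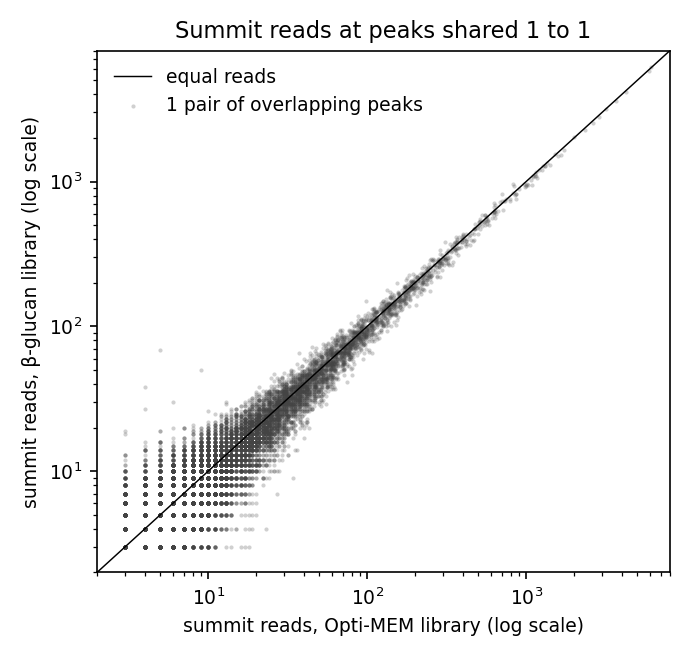
Recovered summit reads of the 13386 peaks shared 1 to 1, in the Opti-MEM library (horizontal axis, log scale) and the β-glucan library (vertical axis, log scale); each point is 1 pair of overlapping peaks and the line marks equal reads. The points lie along the line over the whole range, and the few far above it have under 10 reads in Opti-MEM.

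The tallest peaks had close numbers of summit reads in both libraries. These peaks were singled out after their values were seen. Whether the reads of such tall peaks include duplicates is open, so their numbers need not measure the height of the mark. The intervals given cover counting error only. The peak at chromosome 13, 2412 to 3487, had 6195 summit reads after β-glucan (exact Poisson interval 6042 to 6351) and 6105 in Opti-MEM (5953 to 6260). The peak at chromosome 13, 51935457 to 51936612, had 5809 reads (5661 to 5960) and 5937 (5787 to 6090). The peak at chromosome 25, 17170406 to 17170652, had 4140 reads (4015 to 4268) and 4255 (4128 to 4385).

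The widest domain of the mark lay at the same place in both treatments. It lay at chromosome 1, 28707444 to 28710896. It had 3453 bp and 821 summit reads (766 to 879) after β-glucan, and 3417 bp and 704 reads (653 to 758) in Opti-MEM. The exact Poisson intervals of these reads did not overlap, but they cover counting error only, and the reads may include duplicates. Pairs with 500 or more reads in sum varied by 1.33 times counting variance. With 1 library per treatment the difference cannot be ascribed to the treatment. A domain at chromosome 14, from 52613777 to 52616249, ranked among the 3 widest in both lists, with 2473 bp and 178 reads (153 to 206) after β-glucan and 2477 bp and 188 reads (162 to 217) in Opti-MEM. The second widest β-glucan peak, on an unplaced scaffold from 58778 to 61313, had 94 reads (76.0 to 115) and overlapped an Opti-MEM peak with 118 reads (97.7 to 141). The second widest Opti-MEM peak, at chromosome 2, 56693717 to 56696356, spanned 2640 bp with 52 reads (38.8 to 68.2). The tallest β-glucan peak overlapping it was 817 bp wide with 45 reads (32.8 to 60.2).

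A small number of tall peaks were present in 1 list only, and most of those named here were very narrow. The 3 with the highest −log10 q-value after β-glucan were at chromosome 1, 42209630 to 42209717 (88 bp, 141 reads), chromosome 17, 8604874 to 8604962 (89 bp, 115 reads) and chromosome 14, 14453261 to 14453481 (221 bp, 80 reads). The nearest Opti-MEM peaks lay 15451, 42200 and 49119 bp away. Those of the Opti-MEM list were at chromosome 5, 41964616 to 41964717 (102 bp, 452 reads), chromosome 7, 62505373 to 62505458 (86 bp, 332 reads) and an unplaced scaffold, 19468 to 19552 (85 bp, 232 reads). Their nearest β-glucan peaks lay 3653, 32073 and 1595 bp away. The shortest peak of the β-glucan list was 88 bp and that of the Opti-MEM list 85 bp. The widest list-only β-glucan peak, chosen after its values were seen, was at chromosome 17, 3090719 to 3092209, with 1491 bp and 30 reads (20.2 to 42.8), and its nearest Opti-MEM peak was 33020 bp away. The widest list-only Opti-MEM peak, at chromosome 13, 35339346 to 35340747, had 1402 bp and 8 reads (3.45 to 15.8), and its nearest β-glucan peak was 1022 bp away.

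The distribution of called H3K4me3 peaks along chromosomes was alike in both treatments. Over 256 bins of 5 Mb the numbers of peaks in the lists correlated with Pearson's r = 0.965 and Spearman's rho = 0.937, across bins, which are not independent replicates. Most peaks of each list overlapped the other list, so this correlation partly restates that overlap. Chromosome 23 had the most peaks per Mb (20.2 after β-glucan and 22.6 in Opti-MEM) and chromosome 4 the fewest (8.70 and 9.47). This ranking counts all called peaks and was not tested with taller peaks alone. Chromosome 23 also had the highest mean background at peaks (0.295 and 0.313). Of its peaks, 250 of 932 after β-glucan and 298 of 1045 in Opti-MEM had 10 or more reads. In the whole lists 7859 of 22119 and 8256 of 24434 did. The share of list-only peaks per chromosome ran from 303 of 973 on chromosome 16 (31.1%) to 258 of 679 on chromosome 4 after β-glucan, and from 38.4% on chromosome 12 to 46.2% on chromosome 25 in Opti-MEM.

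The low value of chromosome 4 came from 1 stretch. Its long arm is known as late-replicating heterochromatin rich in repeats. Between 30 and 70 Mb there were 133 β-glucan peaks, or 3.33 per Mb (exact Poisson interval 2.78 to 3.94), and 150 Opti-MEM peaks, or 3.75 per Mb (lower limit 3.17). Before this stretch the density was 14.0 and 15.2 peaks per Mb, and after it 15.8 and 16.6. The 8 bins of the stretch held 12 to 30 β-glucan peaks, where the median of the other 248 bins was 74.5, and 11 to 29 Opti-MEM peaks, where it was 83. The limits of the stretch were chosen after the bins were seen. At its peaks, bin means of the background were 0.134 to 0.147 after β-glucan and 0.141 to 0.162 in Opti-MEM. The floors of the lists were 0.134 and 0.141. Input coverage of the stretch and how well reads map there were not tested, so fewer called peaks need not mean less of the mark.

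**Figure D3:**
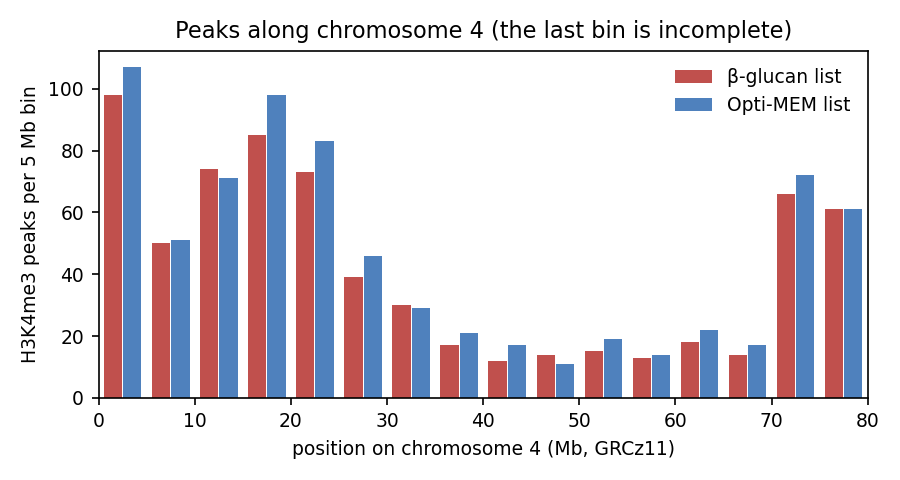
Number of H3K4me3 peaks (vertical axis) in 5 Mb bins along chromosome 4 (horizontal axis, Mb in GRCz11) in the β-glucan and the Opti-MEM list. Both lists fall to between 11 and 30 peaks per bin from 30 to 70 Mb and rise again near the chromosome end.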

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

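The alternatives with 10 or more summit reads, with wider peaks, and for the summit reads of shared peaks were chosen after seeing the data. The Opti-MEM list kept more peaks and a lower shared percentage than the β-glucan list under each stricter threshold, under merging within 500 bp and on the 25 chromosomes alone, but common thresholds on q or fold depend on depth, so that this is no sign of stability. With lists of equal length the shared percentages were 63.1% and 63.1%, which a nearly symmetric overlap of equal lists gives by construction. What moved most was the number of peaks called in 1 list only. In the following, the β-glucan value precedes the Opti-MEM value. With a −log10 q of at least 5 in both lists there were 13419 and 14379 peaks, of which 3459 and 4364 were list-only, and against the full other list 2450 and 3154 were. With a −log10 q of at least 10 there were 8911 and 9238 peaks, 7197 and 7218 of them shared and 1714 and 2020 list-only. A fold of at least 5 left 14323 and 15166 peaks with 3944 and 4736 list-only. With 10 or more summit reads against the full other list, 7349 and 7471 were shared, and 510 and 785 list-only. Among peaks at least 1.5 times as wide as the shortest, 4874 and 6166 were list-only. These filters remove peaks by construction. Reciprocal overlap of 50% left 10683 shared peaks in each list (48.3% and 43.7%) and raised the list-only peaks to 11436 and 13751, so that list-only peaks outnumbered shared ones in both lists. It, a 500 bp tolerance, merging, equal lengths and the chromosomes alone left each count within 1.5 times its value. At shared peaks, the median ratio of reads was 0.972, 0.973 and 0.974 with 100, 200 and 500 or more reads in sum, and the variance over counting variance 0.998, 1.12 and 1.33; the cause was not tested. No paired analysis was possible because each group held 1 library, and for the same reason no replicate could be left out. The planned gene-level alternatives (promoter windows, choice of start site) were not run, since no gene was assigned to a peak. Depth limits all statements on single peaks with under 10 reads.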

Other observations

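The thinning of peaks with 10 or more reads, the counting model for peaks with 20 or more, the narrowness of tall list-only peaks, the split library, the shuffled backgrounds and the models with more reads per call were tests chosen only after the result was seen. Called H3K4me3 peaks gathered at chromosome ends in both treatments. The outer 1 Mb at either end of the 25 chromosomes made up 3.72% of their span, but held 2391 of 21526 β-glucan peaks (exact interval 10.7 to 11.5%) and 2619 of 23818 Opti-MEM peaks (10.6 to 11.4%). Of the 100 tallest peaks on chromosomes, 23 of the β-glucan list and 23 of the Opti-MEM list lay there (15.2 to 32.5% for both), but only 130 and 128 of the 1000 tallest did, close to the share of all peaks. Ends were taken as the first base and the last peak of either list. Input coverage of the ends and how well reads map there were not tested, so more called peaks need not mean more of the mark. The reads of the tallest peaks may include duplicates.

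The first pattern is the smaller β-glucan list and the peaks found in 1 list only. Bounds written beforehand would have excluded counting error at equal rates, which predicted 41.0% of the list-only peaks with under 10 reads (under 50%), and lower coverage, since thinning the Opti-MEM reads to the β-glucan coverage left 23866 peaks, 1747 above the β-glucan list of a gap of 2315. Both were set aside only after this was seen, because fewer peaks at the background floor had 3 reads than 4 (741 against 986 after β-glucan, 887 against 1088 in Opti-MEM), so that the summit may not be the only condition of a call: with 1 more read needed the model predicted 72.1% and thinning left 1049 of the gap, and with 2 more 104% and 431, but list-only peaks with 3 to 4 reads were little narrower than shared ones (38.7% against 33.9% under 1.5 times the shortest width after β-glucan, 38.7% against 32.9% in Opti-MEM), and how many reads such a condition is worth was not measured, which keeps both explanations open. Thinning limited to 10 or more reads, added after the first had failed, left 7937 of 8256 peaks (7906 to 7968 over 100 draws), so that lower coverage is a candidate explanation of most of this gap, but the 7859 after β-glucan lay below every draw. Counting error of independent reads predicted only 0.0551% of the 107 and 177 list-only peaks with 20 or more reads, which argues against it there. The model does not cover the sampling of fragments whose reads are copies. Stacks of reads from 1 fragment are a candidate explanation of the narrow ones among these peaks. Under 1.5 times the shortest width were 43 of the 107 (40.2%) and 106 of the 177 (59.9%), against 17.7% and 17.4% of tall shared peaks (a ratio of at least 2.27). Most of these β-glucan peaks were thus not narrow. Reads in the other input and an effect of treatment were not tested.

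The second pattern is that heights of shared peaks differed little between the libraries, with a variance of 0.929 times the nominal counting variance (0.875 to 0.987) over pairs with 40 or more reads in sum and 1.33 times with 500 or more. Pairs hold only peaks called in both libraries, which limits the differences they can show. In simulated pairs with an assumed summit shape, equal rates gave 0.795 (0.722 to 0.875 over 20 draws), below the observed value, an added coefficient of variation of 5% gave 0.987 and one of 10% gave 1.55. A single amplified library sequenced as 2 would hold each tall stack in both parts, and 76 list-only peaks had 40 or more reads, but reads in the other input could also have kept such peaks from being called; a called pair at chromosome 7, 46679752 to 46680084, with 69 β-glucan and 5 Opti-MEM reads and both backgrounds at the floor goes against a split library, but its summits lay 265 bp apart and how far a background reaches was not established, so the explanation cannot be told apart from others. Chromatin divided before amplification, and a treatment effect that is small or in few peaks, may both give such values and were not tested. No replicate library shows what 2 cultures of 1 treatment would give.

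The third pattern lies in the background, which holds what the inputs contributed. Its mean at peaks ranged from 0.150 reads on chromosome 22 to 0.295 on chromosome 23 in the β-glucan list and from 0.160 to 0.313 on the same chromosomes in the Opti-MEM list, and it differed within chromosomes: on chromosome 16 it was 0.150 ± 0.0021 (standard error over 299 peaks) before 20 Mb and 0.362 ± 0.0066 (511 peaks) from 20 to 50 Mb after β-glucan, where bins of 5 Mb ran from 0.262 to 0.442, and 0.166 ± 0.0035 and 0.370 ± 0.0057 in Opti-MEM, while on chromosome 4 it was 0.152 and 0.293 before 10 Mb and from 10 to 25 Mb after β-glucan, and 0.166 and 0.312 in Opti-MEM. The means of 272 bins of 5 Mb correlated between lists with r = 0.974 (Spearman's rho = 0.946), and their spread was at least 1.32 times the highest of 100 shuffles of peaks within chromosomes, which argues against a property of single peaks; peaks with 5 or fewer reads kept 100.3% of the excess of chromosome 23 over 22 in the list that kept less, which argues against leaking ChIP signal as the whole cause. More copies of these stretches in the cell line are a candidate explanation, but ChIP reads of peaks with 10 or more reads did not clearly rise with background across bins (Spearman's rho of 0.082 after β-glucan and 0.035 in Opti-MEM), a test weakened by the fixed lower limit on reads. Mappability and base composition were not tested, and no biological explanation is given by the design.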
